A study of Homo sapiens with 6 samples.

How the data were processed

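RNA of 6 libraries of SW620, a human colon cancer cell line, was sequenced: 3 from cells with a control vector (shControl) and 3 from cells with a vector against DNM1 (shDNM1). Per the labels' protocols, cells were grown in high-glucose DMEM with serum, RNA was isolated with an RNeasy kit and libraries were made with a SMARTER mRNA-seq kit. Groups were taken from the sample titles. Per the labels, the shControl libraries formed batch_A and the shDNM1 libraries batch_B, so a batch term could not be fitted beside the group.

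The deposited count table holds whole-number read counts per gene, not normalised, with 1 column for each library, as made by the authors on genome build GRCh38 per the submitters' processing notes. The aligner, the counter and the annotation release are not given in the sources used here. It is also not given whether counting used strand, so overlapping and antisense genes are uncertain. The deposited TPM table was treated as a score, because its columns as deposited sum to more than the per-library total that TPM implies. Over unique gene names they sum to 1000000. Among genes with high counts in every library, the only ones checked, the count divided by the TPM differed between libraries by 1 factor. The relative spread of that factor was at most 2.2e-15. Each table had 62710 lines and 60835 unique gene names. In both, 2328 lines shared 453 names with identical values, and these were collapsed to 1 line for each name. The number of unused per-sample columns was 0. Coordinates, KEGG pathway names and Ensembl identifiers are those of the deposited table. Gene types came from RefSeq, which matched 41989 names, 19331 of them protein-coding. GC content came from the longest transcript of each gene in GENCODE release 29 and covered 96.7% of the genes tested.

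Library totals ran from 12844534 to 13537519 counts. Pearson correlations of log2 CPM were at least 0.987 within a group and at most 0.977 between groups. The chi-square per gene of library pairs was 2.42 to 3.54 within shControl, 3.79 to 8.05 within shDNM1 and 18.7 to 23.0 between groups. The shDNM1 libraries thus differed more among themselves. No pair agreed within sampling noise and none was treated as a library deposited again. The share of counts in the 10 most abundant genes was 5.33% ± 0.15 in shControl and 5.62% ± 0.059 in shDNM1 (SD, n = 3).

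Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults, libraries were scaled by TMM, and groups were compared with the two-sided quasi-likelihood F test (glmQLFit and glmQLFTest, robust = FALSE). Every adjusted p of a single gene is from this test with Benjamini-Hochberg adjustment over the 16744 genes tested, at a threshold of 0.05, unless another setting is named. The common biological coefficient of variation was 0.0743. CPM are TMM-scaled, and their SD is over 3 libraries a group. DNM1 was also compared by an exact two-sided permutation test, whose smallest possible p is 0.1 for 3 libraries against 3.

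Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 41 lists, and again with the correlation estimated for each list. The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except those said to have been chosen later. The naming rule took DNM1, DNM2 and DNM3, then the 12 largest rises and 12 largest falls among protein-coding genes with an adjusted p under 0.05, an average log2 CPM of at least 2 and no overlap between groups. For each list it took up to 4 members with the smallest p and, for called lists, the called members that went against the list. KEGG pathways with at least 10 tested genes were examined after the data were seen, with camera and with Fisher's exact test (two-sided) against all tested genes that carry a KEGG pathway.

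Alternatives were other scalings (RLE, upper quartile, library size alone), other low-count filters (none, or a CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, the robust quasi-likelihood fit, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a threshold of 0.01, glmTreat against a 1.5-fold change, fry, the replicate number as a block, and leaving out each library in turn. Removal of GC and gene length trends was added after the data were seen. The gene test was tested on simulated data for this comparison, with 16377 genes tested and 50 genes changed at each size. It called 32% of genes changed 1.25-fold, 60% at 1.5-fold, 76% at 2-fold and 96% at 4-fold, with 8 false calls. Far more genes were called in the real data, where the adjustment is therefore less strict, so these rates need not hold there. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. GO terms of the deposited annotation were not used here, because their column headings appeared to be exchanged. The results of some single genes and of 1 called gene list are not reported here.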

Results

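The samples were SW620, an established human colon cancer cell line derived from a lymph node metastasis. Cells carrying a control short hairpin vector (shControl, 3 libraries) were compared with cells labelled as a stable knockdown of DNM1 (shDNM1, 3 libraries), to find the genes whose mRNA changes when DNM1 is lowered. DNM1 encodes dynamin 1, a GTPase that pinches vesicles off the plasma membrane, and the series title links it to PI3K/Akt signalling in colorectal cancer. Polyadenylated RNA was sequenced and the deposited tables gave a read count per gene, with 12844534 to 13537519 counts in a library. The labels placed all 3 shControl libraries in batch_A and all 3 shDNM1 libraries in batch_B, so the batch and the vector cannot be told apart in any comparison reported here. No label says that the libraries of a group came from separate cultures, and the p-values therefore measure only the spread between these libraries, which may be technical.

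The targeted gene was examined first. DNM1 (ENSG00000106976, GRCh38 chromosome 9, 128191655 to 128255248, plus strand, protein-coding) had 129 ± 3.78 CPM (normalised read counts on a common library total, scaled by TMM; SD, n = 3) in the shControl libraries and 116 ± 16.1 CPM (SD, n = 3) in the libraries labelled shDNM1. Relative to the shControl mean, the shDNM1 libraries held 97.5%, 75.8% and 97.3% of the DNM1 level in replicates 1, 2 and 3. The log2 fold change was -0.15 (SE 0.083) and did not pass the test, with an adjusted p of 0.189. Its 95% interval ran from -0.32 to 0.03, which corresponds to 79.97% to 101.84% of the control level. Each shDNM1 library lay below each shControl library, replicates 1 and 3 by less than 1% of the lowest control, and the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. Replicate 2 set most of the difference: without it the log2 fold change was -0.04 (adjusted p = 0.718), whereas without shDNM1 replicate 1 it was -0.20 and passed the threshold (adjusted p = 0.0399). Because the target mRNA was not clearly lower, the second set is called the libraries labelled shDNM1, and each direction given in this text is between the 2 labelled sets and is not tied to a measured loss of DNM1. Of the other classical dynamins, DNM2, the ubiquitous form, was 1.21-fold higher (adjusted p = 0.00165). DNM3 rose from 3.54 ± 0.28 to 5.25 ± 0.80 CPM (adjusted p = 0.0429), a call that was lost under 11 of 19 other settings, where its adjusted p ranged from 0.0168 to 0.165. For DNM3 these included leaving out shControl replicate 1, 2 or 3 (adjusted p = 0.107, 0.126 and 0.0739) and shDNM1 replicate 1 or 2 (adjusted p = 0.111 and 0.0959).

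**Figure D1:**
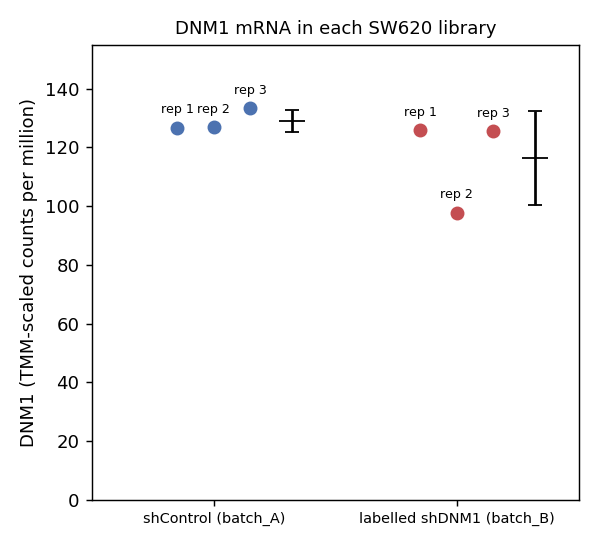
DNM1 mRNA per library, in TMM-scaled CPM on a linear axis from 0, for the 3 shControl libraries of batch_A (blue) and the 3 libraries labelled shDNM1 of batch_B (red); horizontal marks and bars give the mean and SD. The shDNM1 libraries lie at 125.8, 97.8 and 125.5 CPM, against 126.7, 126.9 and 133.4 CPM in shControl.

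Gastrin (GAST), WNT7B, IGF2 and MUC2 were among the genes that rose most in the libraries labelled shDNM1, and ITPR2, APOBEC3B and NR2F1 among those that fell most. GAST, a peptide hormone with growth-promoting effects on gastrointestinal epithelium (chromosome 17, 41712331 to 41715969), went from 0.40 ± 0.15 to 9.20 ± 0.38 CPM, 22.3-fold higher (log2 fold change 4.48, SE 0.27, adjusted p = 1.55e-09). WNT7B, a WNT ligand, was 5.36-fold higher at 71.3 ± 3.54 CPM, and IGF2, the insulin-like growth factor on chromosome 11 (2129112 to 2158391), was 4.90-fold higher at 103 ± 1.27 CPM. The muscle acetylcholine receptor subunit CHRNA1 was 7.56-fold higher, the leukocyte-associated actin-binding protein gene LSP1 5.69-fold and the gel-forming intestinal mucin MUC2 4.72-fold. TH, which encodes the rate-limiting enzyme of catecholamine synthesis, was 3.71-fold higher and HIC1, a transcriptional repressor, 3.57-fold higher. The remaining members of the 12 largest rises were TRPV3, RASGEF1A, SPOCK2 and ALPP, at 3.51-fold to 3.99-fold. ALPP is uncertain, because it has a close paralog, ALPG, with which reads could have been shared.

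Among the genes that fell, ITPR2, an inositol trisphosphate-gated calcium channel of the endoplasmic reticulum (chromosome 12, 26335352 to 26833194), went from 176 ± 15.8 to 31.9 ± 1.54 CPM (log2 fold change -2.46, SE 0.080, adjusted p = 9.95e-13). APOBEC3B, a DNA cytidine deaminase, was 4.83-fold lower at 12.4 ± 2.17 CPM, with the reservation that it belongs to a family of close paralogs. The nuclear receptor gene NR2F1 went from 41.7 ± 3.59 to 9.27 ± 0.93 CPM. The metalloprotease gene ADAMTS18 was 7.93-fold lower, CAPN6 5.45-fold, the collagen gene COL8A1 4.93-fold, the hepatic lipase gene LIPC 4.61-fold and the delta opioid receptor gene OPRD1 4.56-fold. C6orf15, ST18, KRCC1 and GAMT completed the 12 largest falls, at 4.09-fold to 4.80-fold.

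**Figure D2:**
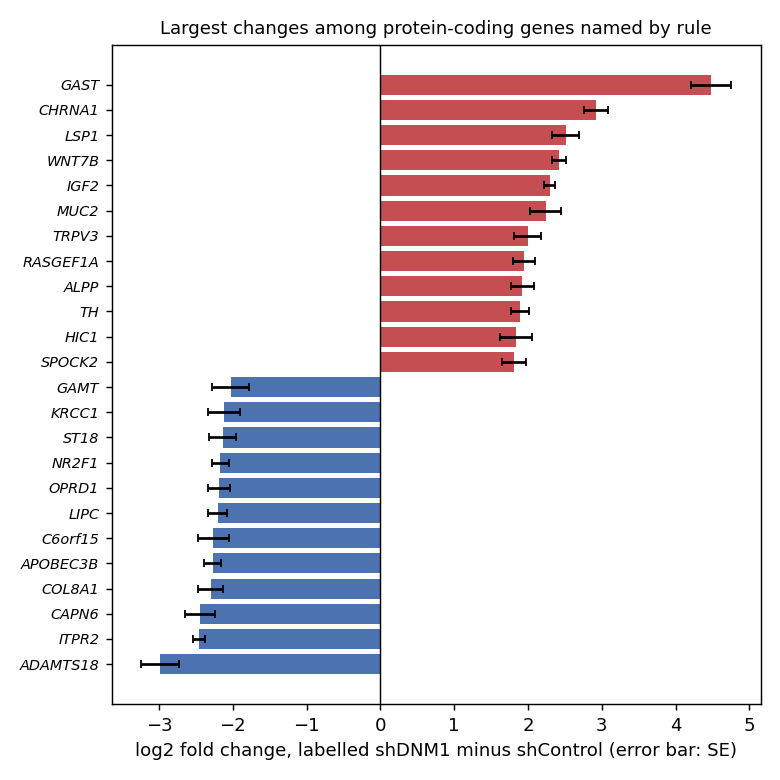
Log2 fold change, labelled shDNM1 minus shControl, of the 12 protein-coding genes with the largest rises (red) and the 12 with the largest falls (blue) by the fixed naming rule; error bars are SE of the fit over 3 libraries a group. The bars run from -2.99 for ADAMTS18 to 4.48 for GAST.

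Of 16744 genes tested, 5337 passed an adjusted p of 0.05, 2617 higher and 2720 lower in the libraries labelled shDNM1, and 6949 had an unadjusted p under 0.05. Most of these differences were small. The median absolute log2 fold change of the called genes was 0.46, 3373 of them changed by less than 1.5-fold, and 806 changed at least 2-fold, 311 higher and 495 lower. The values of the 2 sets did not overlap for 7424 genes (44.3%), where chance gives 10% for 3 libraries against 3. With the deposited TPM values on the log2(TPM + 1) scale in place of scaled counts, limma called 1801 genes higher and 2846 lower, and 417 rather than 806 genes changed at least 2-fold. The first principal component, 54.8% of the variance, separated the 2 sets, whose batches and vectors coincide. The second, 14.9%, placed shDNM1 replicates 1 and 2 furthest apart (25.6 and -27.8). Of all libraries, shDNM1 replicate 2 had the fewest genes with at least 10 counts, 16347 against 16771 to 16896.

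Gene groups fixed before the data were examined were then tested as sets with camera at a preset inter-gene correlation of 0.01. Of 44 lists, 41 had at least 5 tested members, and 13 were called, 11 higher and 2 lower. Splits of the 6 libraries that mixed the 2 sets called 0 genes but still 1 to 11 lists. A list call at the preset correlation is therefore weak evidence by itself. No list was called when the correlation was estimated from the data, and that adjusted p is given beside each of the 12 called lists described. The loss cannot be read as an effect of gene correlation alone. Estimates for the extracellular matrix, mesenchymal and kidney marker lists (-0.0241, -0.0103 and -0.1386) lay below the preset 0.01, yet their calls were lost too. Those of the other called lists described lay above it, from 0.0273 for vesicle trafficking to 0.3712 for MYC and ribosome biogenesis and 0.7536 for mitochondrial genes. For these lists the preset may be too low, and the camera p at the preset then too small. The estimated correlation rests on the few residual degrees of freedom of 6 libraries, so the test that uses it has little power. The counts of members come from the test of single genes over all genes tested.

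Lysosomal and autophagy genes gave the most one-sided count. Of 31 tested members, 19 rose, 0 fell and 12 did not pass, and the count adjusted over the list alone was also 19 (camera adjusted p = 7.07e-05; adjusted p = 0.277 with an estimated correlation). The KEGG lysosome and animal autophagy pathways, examined after the data were seen, were not called (camera adjusted p = 0.156 and 0.557). The lysosomal protease cathepsin D (CTSD) rose from 42.2 ± 2.94 to 89.1 ± 7.80 CPM, and the proton pump subunit ATP6V0D1 from 121 ± 4.81 to 214 ± 7.63 CPM. The autophagy receptor SQSTM1 was 1.72-fold and ATG16L1 1.58-fold higher. In the clathrin endocytosis list, the machinery in which dynamins act, 14 of 33 members rose and 4 fell, against 15 and 4 adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.809 with an estimated correlation). The membrane-bending gene BIN1 was 1.54-fold, the adaptor-binding gene NECAP1 1.68-fold and the clathrin light chain gene CLTB 1.53-fold higher, whereas SNX18, DAB2, SH3GLB1 and ITSN1 fell, SNX18 to 0.554 of its control level. The ITSN1 call was lost without shControl replicate 1 or 2 or shDNM1 replicate 3 (adjusted p = 0.108, 0.0641 and 0.06), and with 3 other settings, and that of SH3GLB1 with a GC or length trend removed (adjusted p = 0.063 and 0.0564). In the vesicle trafficking and recycling list, 13 of 30 rose, among them EHD1 (1.85-fold) and the transferrin receptor gene TFRC (1.38-fold). The 5 that fell were RAB4A, RAB11B, VPS29, SNX1 and SNX2. Adjusted over the list alone, 13 rose and 6 fell (camera adjusted p = 0.0459, and adjusted p = 0.576 with an estimated correlation). The SNX2 call was lost under 12 of 19 other settings, among them leaving out shControl replicate 1 or 3 or shDNM1 replicate 2 or 3 (adjusted p = 0.187, 0.155, 0.139 and 0.0979). Both list calls ended when shControl replicate 1 or 3, or shDNM1 replicate 2 or 3, was left out, with adjusted p values of 0.0505 to 0.077 for clathrin endocytosis and 0.0509 to 0.0757 for vesicle trafficking, and with scaling by library size alone (adjusted p = 0.0633 for each). Of 7 caveolar genes, 4 rose, among them CAV1 (1.28-fold), and CAVIN2 fell to 0.427 of control; adjusted over the list alone, 5 rose and 1 fell, and the list was not called (camera adjusted p = 0.32). In the dynamin family list, 3 of 12 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.998), with the mitochondrial fusion gene MFN1 1.69-fold higher and the endoplasmic reticulum GTPase gene ATL2 at 0.636 of control. Without shControl replicate 3 the members that rose numbered 12 for lysosome and autophagy and 8 for vesicle trafficking, and without shDNM1 replicate 1 those that fell numbered 5 for the dynamin family.

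Of 36 members of the G1-S and DNA replication list, 18 fell, 2 rose and 16 did not pass, against 19 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000373; adjusted p = 0.703 with an estimated correlation). The KEGG DNA replication pathway, examined after the data were seen, was not called, with 13 of 35 genes lower and 4 higher (camera adjusted p = 0.315). The replicative helicase component GINS2 went from 52.9 ± 2.31 to 31.4 ± 2.21 CPM and the thymidine kinase gene TK1 from 198 ± 6.20 to 133 ± 9.93 CPM, and MCM6 fell to 0.698 of control. The 2 that rose were RRM2 and POLA2. The RRM2 call was lost without shControl replicate 2 or without shDNM1 replicate 2 (adjusted p = 0.0527 and 0.0517), leaving 1 member of the list higher. In the mitosis list 5 of 35 fell and 3 rose, and adjusted over the list alone 3 fell and 3 rose (camera adjusted p = 0.908). The cell cycle kinase gene CDK6 was at 0.530 and RB1 at 0.706 of control, and CCND1 was 1.29-fold higher. Their list of 15 genes held CDK inhibitors, D cyclins, CDK4, CDK6 and RB family genes. Of its members 7 fell and 3 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.284). The mitosis counts moved to 7 higher and 8 lower without shDNM1 replicate 1, and to 3, 3 and 2 lower without shControl replicate 1, shControl replicate 3 and shDNM1 replicate 3. Without shDNM1 replicate 1, 5 members of the list with CDK inhibitors and D cyclins rose.

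Of 31 members of the MYC and ribosome biogenesis list, 17 rose, 0 fell and 14 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000373; adjusted p = 0.763 with an estimated correlation). MYC went from 414 ± 12.5 to 613 ± 64.1 CPM, and the spermidine synthase gene SRM was 1.51-fold higher.

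The series title names PI3K/Akt signalling, and mRNA levels of its components did not move in a common direction. Of 35 tested members of the PI3K and AKT core list, 7 rose, 8 fell and 20 did not pass, and adjusted over the list alone 7 rose and 9 fell (camera adjusted p = 0.897). INPP5D, a lipid phosphatase gene, was 1.48-fold higher, and SGK2 was at 0.487 of control. AKT1 and AKT2, named after their values were seen, did not pass, with log2 fold changes of -0.09 (SE 0.064) and 0.08 (SE 0.066). Of 28 genes induced by FOXO factors, which AKT restrains, 6 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.908), with SESN3 1.52-fold higher and CCNG2 at 0.572 of control. These are mRNA levels, and phosphorylation of Akt was not measured in these files. Without shControl replicate 2 or 3, 4 and 3 members of the PI3K and AKT core list rose.

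The KEGG PI3K-Akt pathway, as assigned to genes in the deposited annotation, was examined only after the data were seen. Of its 219 tested genes 51 rose and 41 fell (camera adjusted p = 0.744 over 328 pathways). Called genes made up 42.0% of the pathway against 39.0% of the 5252 annotated genes (odds ratio 1.14, Fisher's exact test adjusted p = 0.724). Enrichment was computed at 3 minimum changes in all. With a minimum of 1.5-fold the odds ratio was 1.72 (40 genes, adjusted p = 0.0454), and with a minimum of 2-fold it was 1.81 (18 genes, adjusted p = 0.187), so that 1 of the 3 passed. Of the 328 pathways, 10 were enriched and 3 depleted among all calls, 17 and 11 at the 1.5-fold minimum and 11 and 3 at the 2-fold minimum. Fisher's test treats genes as independent, which they are not.

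Several upstream inputs of that pathway changed. In the list of receptor tyrosine kinases and ligands, 8 of 23 rose and 5 fell, against 8 and 6 adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.809 with an estimated correlation). The median log2 fold change of this list was only 0.0105 and the mean 0.1946, so the mean rested on a few large rises. Besides IGF2, the ephrin receptor gene EPHA2 went from 333 ± 19.7 to 687 ± 50.4 CPM and the EGFR ligand gene EREG from 28.8 ± 4.04 to 69.7 ± 3.17 CPM, whereas ERBB2 fell from 85.0 ± 1.76 to 44.2 ± 2.22 CPM. INSR, EPHB4, DDR1 and IGF1R also fell, the last to 0.889 of control, a call lost under 11 of 19 other settings with adjusted p values from 0.0103 to 0.481 over all 19. For IGF1R these included leaving out shControl replicate 1, 2 or 3 (adjusted p = 0.061, 0.158 and 0.121) and shDNM1 replicate 2 or 3 (adjusted p = 0.0534 and 0.0854). The list call ended without shControl replicate 1, shDNM1 replicate 2 or shDNM1 replicate 3 (adjusted p = 0.0858, 0.0505 and 0.0577) and with scaling by library size alone (adjusted p = 0.0633). Of 27 extracellular matrix and integrin genes 11 rose and 3 fell, against 11 and 4 adjusted over the list alone (camera adjusted p = 0.00455; adjusted p = 0.277 with an estimated correlation). The laminin chain genes LAMA3 and LAMB2 were 2.11-fold and 1.75-fold higher and the fibronectin receptor subunit ITGA5 1.61-fold higher, whereas THBS1, COL4A2 and ITGA1 fell, THBS1 to 0.276 of control.

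Of 16 tested mesenchymal genes 7 rose and 2 fell, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.0313; adjusted p = 0.362 with an estimated correlation). The transcription factor gene SNAI2 was 2.70-fold and TGFB1 1.46-fold higher, whereas TGFBI was at 0.559 and VIM, the mesenchymal intermediate filament gene, at 0.805 of control. Of 28 epithelial junction genes 8 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.897), with CLDN1 1.43-fold and JUP 1.47-fold higher and CLDN3 at 0.388 of control. Of 24 glycolysis genes 9 rose and 1 fell, against 10 and 1 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.809 with an estimated correlation). The lactate exporter gene SLC16A3 was 1.73-fold, the glucose transporter gene SLC2A3 1.69-fold and HK1 1.68-fold higher, whereas the phosphofructokinase gene PFKL fell to 0.585 of control. The KEGG glycolysis and gluconeogenesis pathway, examined after the data were seen, had 8 of 42 genes higher and 9 lower (camera adjusted p = 0.93). Metalloprotease and invasion genes moved both ways, 6 higher and 6 lower of 19 and 6 and 7 adjusted over the list alone (camera adjusted p = 0.785), with L1CAM 2.38-fold higher and CD44 at 0.348 of control. Of 28 WNT target genes 6 rose and 9 fell, against 7 and 11 adjusted over the list alone (camera adjusted p = 0.224), the stem cell marker LGR5 to 0.524 of control and SMOC2 to 0.450, with APCDD1 2.55-fold higher. Of 28 RAS-ERK output genes 9 rose and 7 fell, against 10 and 7 adjusted over the list alone (camera adjusted p = 0.151), with HMGA2 2.70-fold higher and SPRY1 at 0.412 of control. Epithelial junction genes that fell numbered 3 without shControl replicate 1 and 2 without shControl replicate 2, shControl replicate 3 or shDNM1 replicate 3, and glycolysis genes that fell numbered 2 without shDNM1 replicate 2.

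**Figure D3:**
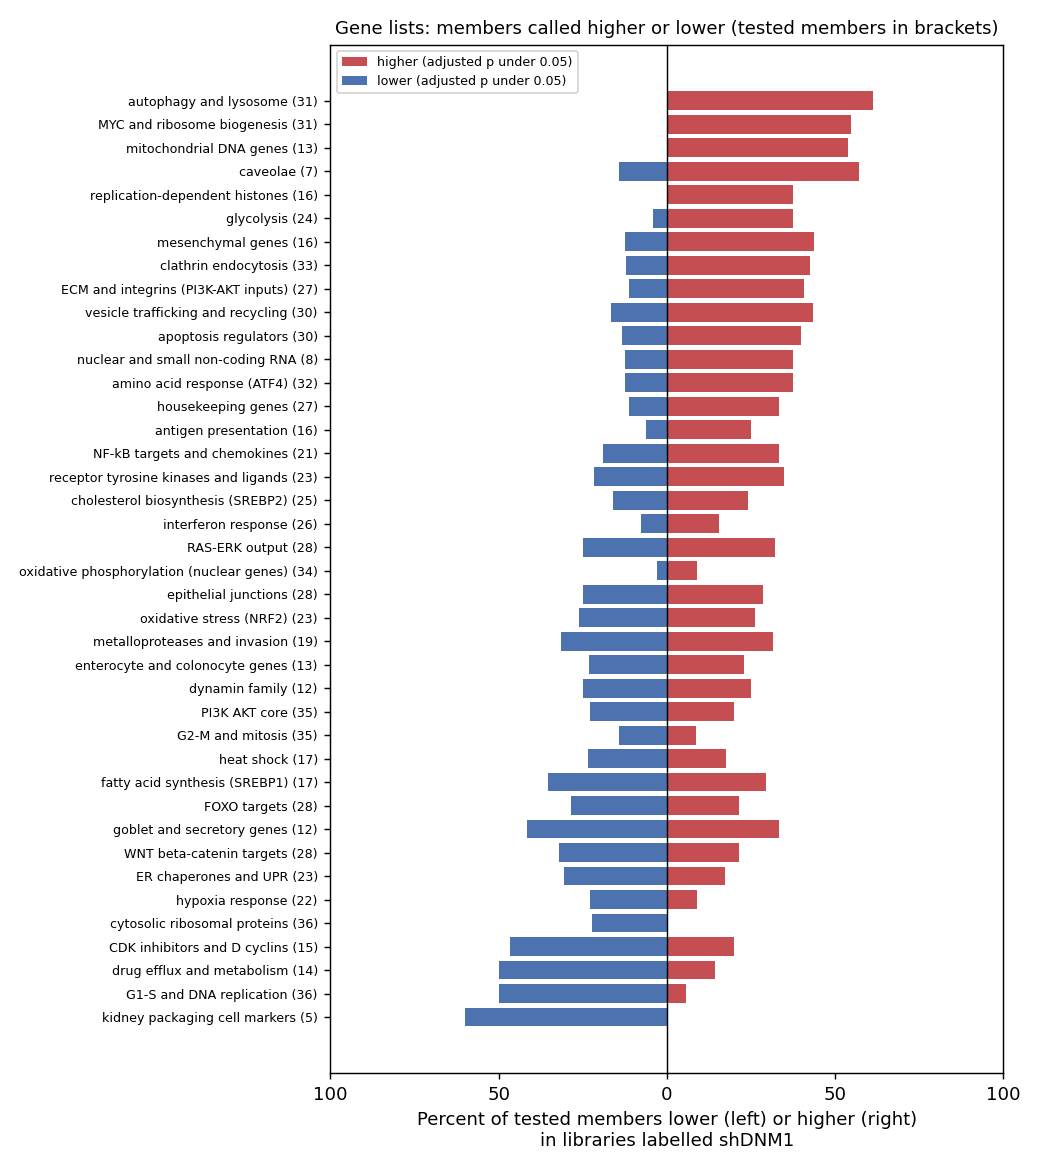
Percent of tested members of each gene list shown that were called higher (red, to the right) or lower (blue, to the left) in the libraries labelled shDNM1 at an adjusted p under 0.05, with the number of tested members in brackets. The autophagy and lysosome list has 19 of 31 members higher and 0 lower, and the G1-S and DNA replication list 18 of 36 lower and 2 higher.

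RNA composition differed between the sets as well. Transcripts of mitochondrial DNA took 3.42% ± 0.018 of counts in shControl and 3.84% ± 0.16 in the libraries labelled shDNM1 (SD, n = 3), and 7 of 13 mitochondrial genes rose and 0 fell, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.852 with an estimated correlation). That list call ended without shDNM1 replicate 2 (adjusted p = 0.19). The list was also not called with fry (adjusted p = 0.18), which tests a list against no change rather than against other genes. Ribosomal protein genes took 4.32% ± 0.16 and 3.93% ± 0.16 of counts, and 0 of 36 rose and 8 fell, or 6 adjusted over the list alone (camera adjusted p = 0.32). Of 16 tested replication-dependent histone genes, whose main transcripts lack a poly(A) tail, 6 rose and 0 fell, against 7 and 0 adjusted over the list alone (camera adjusted p = 0.000373; adjusted p = 0.277 with an estimated correlation). H2BC21 was 3.36-fold and H2AC6 2.87-fold higher, values that are uncertain because histone genes are near-identical. The signal recognition particle RNA RN7SL1 was 1.90-fold higher, a value that is uncertain because it has a near-identical copy, RN7SL2. In the list of 8 non-coding RNAs that holds RN7SL1, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.391). Of 27 housekeeping genes 9 rose and 3 fell, against 10 and 4 adjusted over the list alone (camera adjusted p = 0.284). Without shControl replicate 2 or shDNM1 replicate 2, 1 and 3 mitochondrial genes fell. Ribosomal protein genes that fell numbered 3, 5 and 3 without shControl replicate 2, shControl replicate 3 and shDNM1 replicate 3, and 1 rose without shDNM1 replicate 1.

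Markers of other cell types were mostly too low to test. Of the fibroblast, leukocyte and endothelial lists 4, 2 and 4 members were tested, with 3, 1 and 2 higher and 0, 1 and 0 lower, the same counts as adjusted over each list alone. Of the 2 endothelial risers, VWF (adjusted p = 0.049) was lost under 11 of 19 other settings, among them leaving out shControl replicate 1 or 2 or shDNM1 replicate 1 or 3 (adjusted p = 0.162, 0.159, 0.0652 and 0.194), and 1 endothelial gene fell without shDNM1 replicate 1. Of the 3 fibroblast risers, LUM was lost without shControl replicate 2 or shDNM1 replicate 1 (adjusted p = 0.067 and 0.0628). FBLN1, a fibroblast marker, went from 51.4 ± 0.41 to 80.5 ± 5.83 CPM, while the means of PDGFRB, CSF1R and TIE1 stayed at or under 4.93, 3.92 and 4.12 CPM. The kidney markers, included because lentiviral packaging cells could carry over, had 0 of 5 higher and 3 lower, or 4 adjusted over the list alone (camera adjusted p = 0.0459; adjusted p = 0.46 with an estimated correlation). These were HOXD10 and SIX2, both under 2 CPM, and the calcium-binding protein gene CALB1, which was abundant at 429 ± 30.7 and 293 ± 69.4 CPM; its call was lost in the robust quasi-likelihood fit (adjusted p = 0.0759). That list call ended without shControl replicate 1 or 3 or shDNM1 replicate 2 or 3 (adjusted p = 0.0505 to 0.0757) and with scaling by library size alone (adjusted p = 0.0633).

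The 15 lists described next were not called by camera. Members higher and lower were 12 and 4 of 30 for apoptosis regulators (the death receptor gene TNFRSF10A 1.73-fold higher), 12 and 4 of 32 for the ATF4 amino acid response (PHGDH at 0.471 of control), 4 and 7 of 23 for endoplasmic reticulum chaperones (PDIA4 at 0.652) and 3 and 4 of 17 for heat shock. They were 6 and 6 of 23 for NRF2 targets, 4 and 2 of 26 for the interferon response, 4 and 1 of 16 for antigen presentation (its transactivator gene NLRC5 3.27-fold higher) and 7 and 4 of 21 for NF-kB targets. They were 6 and 4 of 25 for cholesterol synthesis, 5 and 6 of 17 for fatty acid synthesis (the desaturase gene FADS1 at 0.482 of control), 2 and 5 of 22 for hypoxia and 3 and 1 of 34 for oxidative phosphorylation. They were 3 and 3 of 13 for colonocyte genes (the intestinal transcription factor gene CDX2 2.47-fold higher), 4 and 5 of 12 for goblet and secretory genes (MUC13 at 0.301 of control) and 2 and 7 of 14 for drug efflux and metabolism. Adjusted over the list alone they were 5 and 9 for endoplasmic reticulum chaperones, 4 and 4 for heat shock, 7 and 7 for NRF2 targets, 4 and 3 for antigen presentation, 4 and 5 for hypoxia, 2 and 1 for oxidative phosphorylation, 3 and 4 for colonocyte genes and 2 and 8 for drug efflux and metabolism, and did not differ for the other 7 lists. Their camera adjusted p values ran from 0.0547 for apoptosis regulators to 0.998. For 6 lists the median, the mean and the camera direction differed in sign, namely fatty acid synthesis, epithelial junctions, metalloproteases and invasion, heat shock, NRF2 targets, and goblet and secretory genes. Many of these member counts moved by over 1.5 times when a library was left out. Members that rose numbered 2 for cholesterol synthesis without shControl replicate 1, 5 for hypoxia and 6 for oxidative phosphorylation without shDNM1 replicate 1, and 1, 2 and 2 for endoplasmic reticulum chaperones without shControl replicate 1, shControl replicate 3 and shDNM1 replicate 3. For antigen presentation they numbered 2, 1 and 2 without the same libraries. Of its risers, B2M was lost without shControl replicate 1, 2 or 3 or shDNM1 replicate 1 or 2 (adjusted p = 0.106, 0.094, 0.169, 0.0696 and 0.0623), and HLA-C without shControl replicate 1 or 3 or shDNM1 replicate 2 or 3 (adjusted p = 0.17, 0.143, 0.137 and 0.0907). For drug efflux and metabolism the members that rose numbered 0 without shControl replicate 3 and 1 without each other library but shDNM1 replicate 1. Members that fell numbered 2, 0 and 2 for apoptosis regulators without shControl replicate 1, shControl replicate 3 and shDNM1 replicate 3, and 4 and 3 for endoplasmic reticulum chaperones without shControl replicate 1 and 2. They numbered 2 for heat shock and for cholesterol synthesis without shControl replicate 3, and 2, 3 and 2 for hypoxia without shControl replicate 3, shDNM1 replicate 2 and shDNM1 replicate 3. They numbered 2, 2 and 3 for antigen presentation without shControl replicate 1, shDNM1 replicate 1 and shDNM1 replicate 2, and 1 for colonocyte genes without shControl replicate 1 or 2 or shDNM1 replicate 2 or 3. They numbered 3 for goblet and secretory genes without shControl replicate 3 or shDNM1 replicate 3, and 0 for oxidative phosphorylation without shDNM1 replicate 3.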

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

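The GC and length trend removals and the KEGG fold minimums were chosen after the results were seen; the other settings were planned. The number of calls was 4636 to 6080 over all other settings at the 0.05 threshold with all 6 libraries, 3990 to 5890 when a library was left out, and 3503 at a threshold of 0.01, which is stricter by construction. DESeq2 called 4710 genes, 4674 of them among the 5337, and no setting called one of these in the opposite direction. Changes of at least 2-fold numbered 417 with limma-trend on log2(TPM + 1), whose pseudocount shrinks low genes by construction, 799 with a pseudocount of 0.1, 591 with glmTreat and 741 to 908 without a library. Library size scaling, GC and length trend removal gave 42.1%, 56.8% and 58.2% of calls higher, and DNM1 stayed from -0.22 to -0.09 with all 6 libraries, not passing in any of these settings. Without a library the DNM1 log2 fold change ran from -0.2049 (without shDNM1 replicate 1, adjusted p = 0.0399) to -0.0373 (without shDNM1 replicate 2). Lists called numbered 0 with the correlation estimated for each list, 9 to 16 in the other settings and 9 to 14 without a library. Of the 13 called lists, 8 stayed called in all 11 settings other than the estimated correlation. Those settings include fry, which asks a different question from camera, namely whether a list changed at all. Of 209 named genes other than DNM1, over all settings, 116 gene-setting pairs lost a call, 3 gained one (ENG in 1 setting, GATA3 in 2) and 6 changed sign; DNM1 gained a call only without shDNM1 replicate 1. Signs changed for genes that were not called: COL1A1 ran from -0.0239 to 0.1913 and PECAM1 from -0.077 to 0.0701 without a library, and PECAM1 was 0.0359 with the GC and 0.0564 with the length trend removed; the cause was not tested. The KEGG PI3K-Akt odds ratio passed at the 1.5-fold minimum (1.72) and not at the 2-fold minimum (1.81). As a replicate block, the replicate number gave 6080 calls, more than the 5337 without it, 830 at least 2-fold, and 13 lists. DNM1 was then at -0.16 (adjusted p = 0.0629). Libraries with the same number had deviations correlated at 0.102, 0.063 and -0.033. Those of libraries with different numbers were not set beside them, so whether the numbers pair the libraries was not settled. Small changes may be missed: in simulated data with 50 genes changed at each size, 60% of genes changed 1.5-fold and 76% changed 2-fold were called. These rates need not hold here, because the adjustment is less strict when as many as 5337 genes are called.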

Other observations

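The tests of the chromosome 11 run, the KEGG pathways and the GC and length trend removals were chosen after the results were seen. Over 328 KEGG pathways camera called 5, and 0 with an estimated correlation (adjusted p = 0.997 for each), a setting with little power in 6 libraries. Proteasome genes had 16 of 36 members higher and 0 lower (camera adjusted p = 0.0316), among them the regulatory subunit gene PSMD2 at 1.39-fold and the catalytic subunit gene PSMB5 at 1.29-fold. Phagosome genes had 36 of 80 higher and 5 lower (camera adjusted p = 0.0108), among them the tubulin gene TUBB6 at 1.94-fold and the proton pump gene ATP6V1D at 1.59-fold. Ribosome biogenesis genes had 28 of 68 higher and 3 lower, and synaptic vesicle cycle genes 18 of 47 higher and 3 lower (camera adjusted p = 0.0316 for each). Other pathways close to called lists were not called: lysosome (38 higher and 12 lower of 114, camera adjusted p = 0.156), endocytosis (66 and 27 of 203, 0.158), DNA replication (4 and 13 of 35, 0.315), ECM-receptor interaction (15 and 10 of 49, 0.544) and animal autophagy (36 and 19 of 121, 0.557). In the pathway named primary immunodeficiency 0 of 16 were higher and 8 lower (camera adjusted p = 0.0113), among them the DNA repair gene UNG at 0.579 and the T-cell kinase gene LCK at 0.719 of control.

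Cytokine and cytokine receptor genes changed in both directions, 26 higher and 31 lower of 108 tested (camera adjusted p = 0.995). Genes changed at least 1.5-fold made up 35.2% of this pathway against 11.8% of annotated genes (odds ratio 4.26, Fisher's exact test adjusted p = 2e-08, with genes treated as independent); at least 2-fold changes gave an odds ratio of 3.57 (adjusted p = 0.00592) and all calls 1.77 (adjusted p = 0.0808), in the same tests of 328 pathways as PI3K-Akt. The stress cytokine gene GDF15 was 2.75-fold, the activin subunit gene INHBB 1.83-fold and the ectodysplasin receptor gene EDAR 2.16-fold higher, whereas the receptor genes ACVR2B and BMPR2 were at 0.516 and 0.514 of control.

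The first pattern is that 5337 genes differed between the sets. After GC content and gene length trends were removed, 5853 and 5402 genes were called. Of the main calls in the genes fitted, 4873 of 5256 and 4851 of 5337 stayed called in the same direction, which argues against either bias as the whole cause. Only 0.37% of placed calls lay in runs of neighbouring genes beyond shuffled orders, which argues against large copy-number differences over long segments as the whole cause. Changes that left the median of a 31-gene window within 0.3451 could not be seen in that way, nor could effects on genes elsewhere. The batch difference stays open, because 0 batches hold libraries of both groups, and so does an effect of the vector: the 2 cannot be told apart. Of the 10 splits of the 6 libraries, 1, the real one, gave as many calls (5337, highest other 0), 1 as many at least 2-fold changes (806, highest other 0) and 1 as many lists (13, highest other 11), and 10 splits are too few for a share under 0.05. The other splits called 0 genes but each called 1 to 11 lists, so list calls at the preset correlation are weak evidence by themselves.

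The second pattern is that DNM1 mRNA was not clearly lower in the libraries labelled shDNM1. Swapped labels of single libraries between the groups are argued against by the 0 libraries whose closest library belonged to the other group, and scaling that hides a fall by the lowest log2 fold change over the scalings, -0.2157. Whether the other changes scale with the loss of DNM1 stays open: the left-out slope of shDNM1 replicate 2, the library with the lowest DNM1, was 0.7619, between those of replicates 1 and 3 (0.70 and 0.7951). Protein was not measured in these files.

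The third pattern is a run of neighbouring genes on chromosome 11 (1223066 to 2397802, band p15.5), found with sliding windows of 31 genes, whose largest absolute window median was 0.64 (log2; permutation p = 0.001, the smallest that 1000 shuffles of gene order give). The 20 genes at the centres of windows whose median passed the limit from shuffled orders (0.3451) included IGF2, TH, LSP1 and CTSD, 13 higher and 2 lower in the libraries labelled shDNM1. Of 30 flanking genes 11 were higher, among them MUC2, MUC5AC, CDKN1C, SLC22A18 and PHLDA2, 3 were lower, among them PIDD1 and OSBPL5 (log2 fold changes -0.46 and -0.81), and 16 did not pass, among them KCNQ1OT1 (-0.10) and TSSC4 (0.08). An equal copy-number gain over the whole run as the only cause is argued against, but weakly, by its 2 lower called genes, MRPL23 and LINC01219. MRPL23 overlaps another expressed gene, so its reads are uncertain. LINC01219 was low, at 3.33 CPM in shControl and 1.86 CPM in the libraries labelled shDNM1. The run's changes were also uneven, with log2 fold change quartiles of 0.1754 and 1.3172. Reads shared between overlapping genes as the only cause are argued against by the 9 of its 13 higher genes that overlap no other expressed gene. A gain together with other changes and the batch stay open, and no other explanation was tested.

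A second run on chromosome 19 (21142024 to 23250394) had 7 genes, 0 called higher and 3 lower, with a median of -0.27.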
